A study of Mus musculus with 16 samples.

How the data were processed

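Spleen cells of 9-month-old female BALB/cJ mice were profiled by CITE-seq, a droplet method that reads polyadenylated RNA and DNA-tagged antibodies from the same cell. The labels describe 16 samples in 4 groups of 4, namely RNA and antibody-tag samples for each of 2 sources, Main1 and Main2. Per the labels' protocols, tissue was pressed through a 40 um strainer, red blood cells were lysed for 5 minutes, and cells of the pellet were stained with the antibody panel. In each group the sample titles carry 2 codes that read as dates, with 2 samples each, and Main1 and Main2 share both. The deposited tables do not separate them, so a difference between dates could not be checked. The labels do not say whether Main1 and Main2 are different animals. P-values here therefore cover at most the spread between these libraries, in most comparisons as a trend shared across genes.

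The deposited tables held 1 count per gene and droplet and 1 count per antibody and droplet. Both were whole numbers with no normalization, the first being unique molecular identifiers (UMIs) and the second antibody tags. The submitters' processing notes name bcl2fastq, Cell Ranger 3.0.2 and the mm10 genome build. The counter used for antibody tags is not given in the sources used here. Droplet names began with m1 or m2, and these prefixes were read as Main1 and Main2. The 4 samples of a group could not be told apart in the deposited tables, so each source was treated as 1 library. Every listed gene had a UMI in at least 15 droplets and 0 mitochondrial genes were listed, so the table had been filtered before deposit. No further filter on droplets was applied. Of 11713 gene identifiers, 11682 matched a symbol in the GENCODE vM21 annotation of GRCm38 (mm10), and 31 did not. Coordinates are 1-based positions in that annotation.

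The main gates, the gene lists of the report, cell type markers, main tests and the rule for named genes were set before the data were examined. Settings and tests added later are named as such. UMIs were scaled to 10000 per droplet and log-transformed. Leiden clustering used scanpy 1.11.5 and igraph 0.11.9 on 2000 variable genes, of which 1924 were left once immunoglobulin and T-cell receptor genes were removed. It took 30 principal components, 15 neighbours and a resolution of 1, and gave 22 clusters. A cluster was called X-like for the class whose fixed markers had the highest mean standardized level in it. At least 3 of them had to reach double the level of the lower-quartile cluster. Scrublet marked 4 of 7097 droplets (0.0564%). Either the caller did not work on these data or such droplets had been removed in part before deposit, which was not tested. Removal was not complete by the antibody gates described next. With these, 346 droplets (170 in Main1, 176 in Main2) were positive for CD3, a B-lineage antigen and CD4 or CD8a. All droplets were kept, and droplets holding more than 1 cell were not removed here.

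Antibody counts were put on a centred log-ratio scale across droplets. A Gaussian mixture of 2 components gave antibody-positive droplets (posterior above 0.5, scikit-learn 1.9.0). The T gate took droplets positive for CD3 and negative for B-lineage antigens, among them B220, and was divided by CD4 and CD8a. The B gate took droplets positive for at least 1 of the same antigens and negative for CD3. Within it, the marginal zone gate took the top 25% of CD21/35 with IgD under the median. The follicular gate took IgD at or above the median with CD21/35 below that top 25%. CD44-high and CD44-low droplets were the upper and lower tertile of CD44 within the CD4 and the CD8 gate.

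UMIs were summed per library and gated population, and edgeR 4.0.16 quasi-likelihood tests (R 4.3.3) were run on the sums, with the library as a block. Both populations of a comparison came from the same libraries, so the block pairs them by construction, and 1 residual degree of freedom remained. The prior degrees of freedom were infinite in the 3 T-cell fits and 20.9 in the B-cell fit. With an infinite prior each gene takes the shared variance trend, so a gene seen in 1 droplet of 1 library can reach a very small p-value. The share of UMIs in the top droplet and the ratio in each library are therefore given where they bear on a gene. Genes with 50 or more UMIs over both populations were tested, at a Benjamini-Hochberg adjusted p under 0.05. Fixed gene lists were tested with camera (limma 3.58.1) at its preset correlation and again with an estimated correlation. The estimate rested on the 1 residual degree of freedom, so a list could hardly pass with it. Its lowest unadjusted camera p over all lists was 0.058, for erythroid genes in the B-cell comparison. Values with an estimated correlation therefore decide nothing about a list, and those at the preset correlation assume a correlation that was not measured. Ratios of pooled CPM (UMI sums scaled to the same total) were computed as log2 of (CPM + 10). Their intervals were exact conditional binomial, and intervals of shares were Clopper-Pearson, both at 95%. All such intervals cover counting error only. A ratio against a count of 0 was set against a floor of 3 UMIs over the whole population, a floor chosen after the data had been seen. Antibody and mRNA were related by Spearman's rho over droplets, with no p-value, since droplets are not replicates. Main1 against Main2, with 1 library each, had no test.

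The named genes of a comparison were the 10 with the highest and the 10 with the lowest log2 ratio among genes of 50 or more UMIs, with the same sign in both libraries. Genes of the gating antigens and receptor segments were left out of that rule. For each antibody 5 genes were named, and for Main1 against Main2 5 each way in classes of at least 100 droplets. Members of the fixed lists were named as examples. Of the fixed lists, those with 3 or more tested genes were tested. In the gated comparisons, counts of list genes cover their tested members alone. Members under 50 UMIs, such as Foxp3 for CD44 in the CD4 gate (17 against 4 UMIs), are not among them. Near-identical gene pairs, such as Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt, or Ly6c1 and Ly6c2, share sequence, so the division of UMIs between them is uncertain.

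The procedures were tested on simulated data with 200 changed genes. Counts were drawn from the negative binomial model with the fitted common dispersion, so the recovery given here does not cover genes carried by single droplets. The edgeR step recovered 24% of 2-fold and 75% of 4-fold changes for CD4 against CD8 T cells over 2023 genes, with 1 false call. For marginal zone against follicular B cells it recovered 68% and 88% over 6506 genes, with 5 false calls. For CD44 it recovered 72% and 99% over 1110 genes in the CD4 gate, with 18 false calls, and 44% and 93% over 298 genes in the CD8 gate, with 2 false calls. The rank procedure placed the source gene first for 200 of 200 simulated antibodies. These were drawn from the counted UMIs of abundant genes, so this outcome could hardly have been otherwise. It does not cover sparse cognate genes such as Cd4 (543 UMIs) or Cd5 (490 UMIs). The counting interval held the known ratio for 190 of 200 genes.

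Other settings fixed in advance were k-means gates, a log-ratio within each droplet, raw antibody counts, thinning to 1100 UMIs, other clustering settings, pseudocounts of 1 and 50 CPM, minimums of 10 UMIs or none, means over droplets, narrower gates, Scrublet calls left out, and DESeq2 1.42.0 for the T-cell lineages. Added after the data had been seen were droplets under 4000 UMIs alone, droplets of the gate's own mRNA class alone, fits without the library block, values within each library, and DESeq2 and UMI minimums for the other gates. With 2 libraries, leaving 1 out leaves no residual degree of freedom, so those are values with no test.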

Results

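The 2 libraries held 7097 droplets of spleen cells in which 11713 genes and 30 antibodies had been counted. Main1 had 3179 droplets, 7964712 UMIs in total and a median of 1789 UMIs per droplet. Main2 had 3918 droplets, 10174799 UMIs and a median of 1778. Antibody counts came to 15028386 in Main1 and 17467311 in Main2, with medians of 3379 and 3106.5 per droplet. The study title names the mapping of antigens from multiplexed tissue images to transcriptomes. The comparisons below ask how each antigen related to its own transcript and which transcripts set apart populations gated on antigens alone.

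B cell-like droplets, with Cd79a, Ms4a1 and Pax5 among their markers, were the largest class at 5309 droplets, 74.8% of all (95% interval 73.8 to 75.8). Their share was 73.6% in Main1 and 75.8% in Main2. T cell-like droplets numbered 871, 12.3% of all, with 13.3% in Main1 and 11.5% in Main2. The myeloid classes were monocyte-like (167 droplets), red pulp macrophage-like (101), conventional DC2-like (89), neutrophil-like (80), plasmacytoid DC-like (53), conventional DC1-like (35) and basophil or mast-like (17). NK-like droplets numbered 150, erythroid-like 142 and plasma cell-like 83. A B-like cluster of 743 droplets had 8 of 10 marginal zone markers at 2 or more times the level of other B-like droplets. Another B-like cluster, of 154 droplets, had 8 of 10 interferon response genes at that level. Median depth differed between classes, from 1633.5 UMIs in NK-like to 7198 in plasma cell-like droplets. With 4000 variable genes the conventional DC2 name was lost, so that class depended on the clustering. The name was also a narrow choice, since stem or progenitor markers had nearly the same mean standardized level in that cluster. Of 6 measured conventional DC2 markers 5 reached the required level, but none was among the 10 leading genes of the cluster.

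Antibody counts, which took no part in the clustering, followed the mRNA classes. B220, the B-lineage form of CD45, had a median of 580 counts in B-like droplets against 30 in all others, and CD79b was positive in 99.5% of them. In T-like droplets the medians were 1586 for CD90, 381 for CD5, 343 for CD4 and 120 for the T-cell receptor, and 96.4% were receptor-positive. Ly6G, a neutrophil antigen, had a median of 1526 in neutrophil-like droplets and no more than 13 in any other class. Ly6C was highest in monocyte-like (1768) and plasmacytoid DC-like droplets (846). F4/80 and CD106, the product of Vcam1, had medians of 477 and 239 in red pulp macrophage-like droplets. CD11c reached 255 in conventional DC2-like and 127 in conventional DC1-like droplets, and the median of CD8a in the latter was 75, against 3 in conventional DC2-like droplets. MHC class II was highest in conventional DC2-like droplets, the class of uncertain name, at a median of 2404. The transferrin receptor CD71 had a median of 179.5 in erythroid-like droplets. Several gates were poor. The NKp46 gate opened at 1 count and took 47.3% of all droplets, although the NK-like median was 10 against 1 or 0 elsewhere, and the CD45 gate also took droplets with 1 count. Positive shares also depended on the method: with the mixture and on a log-ratio within each droplet they were 14.2% and 85.5% for CD16/32, 9.17% and 87.4% for CD31, 6.5% and 60.1% for CD169, and 24.5% and 68.4% for ERTR7.

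**Figure D1:**
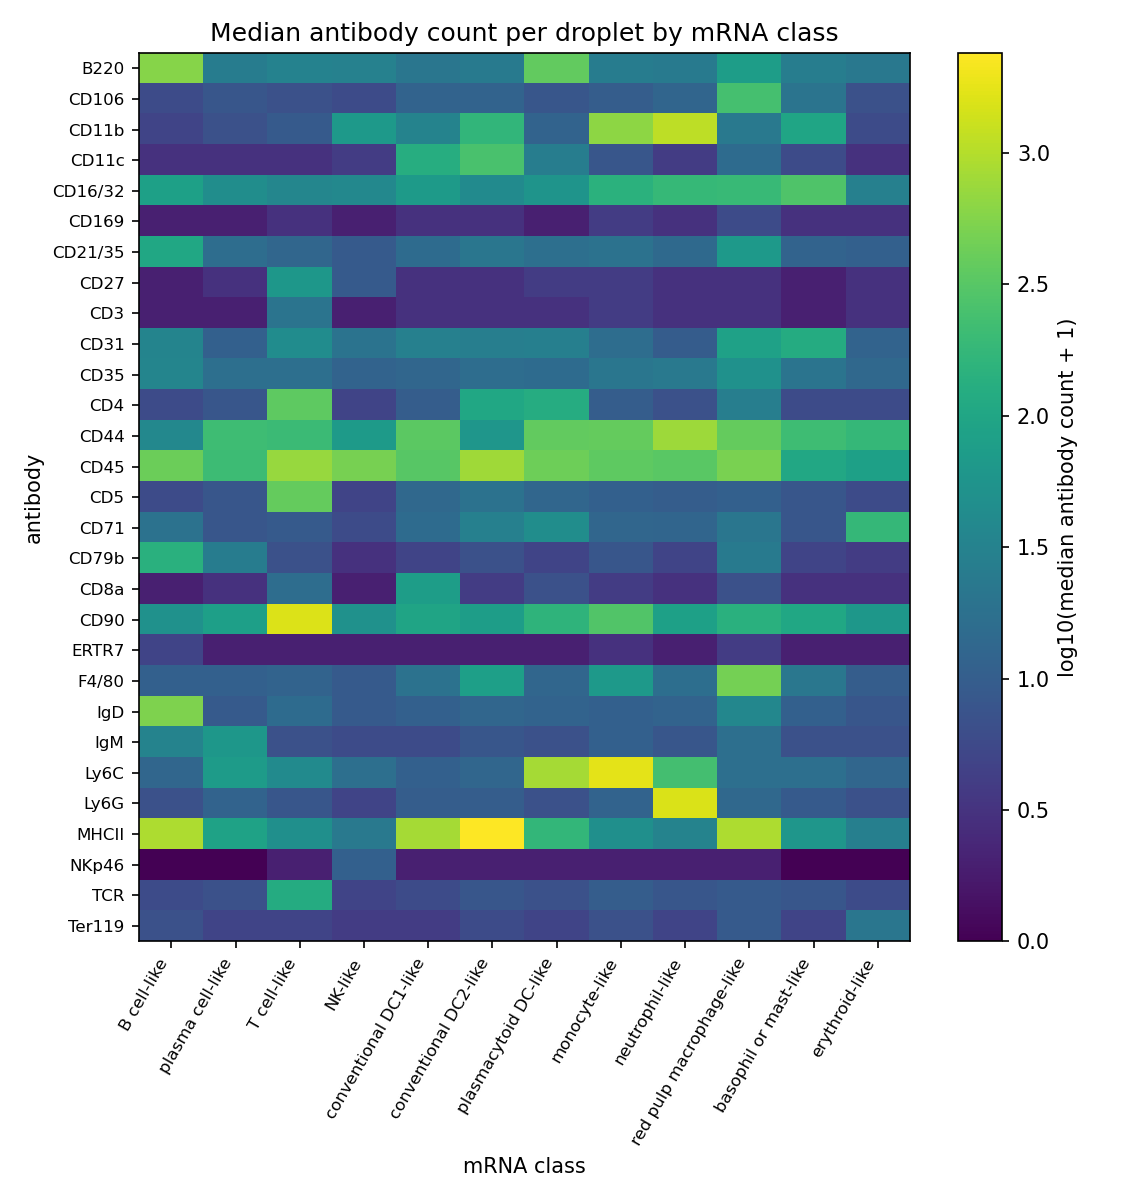
Median antibody count per droplet (colour, log10 of the median plus 1) with antibodies in rows and 12 mRNA classes in columns. Ly6G stands out in neutrophil-like droplets (median 1526) and CD90 in T cell-like droplets (median 1586).

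Across all droplets, 27 antibodies had a measured cognate gene, and the median Spearman rho between antibody and cognate mRNA was 0.311. The highest values were those of IgD with Ighd (0.556), CD21/35 with Cr2, the complement receptor gene (0.487), IgM with Ighm (0.478), CD3 with Cd3e, Cd3d and Cd3g (0.473) and the T-cell receptor with Trbc1 and Trbc2 (0.467). In all, 14 antibodies exceeded 0.3. For 8 antibodies the best cognate gene ranked first of all 11713 genes, among them Ncr1 for NKp46, at a rho of 0.248. Lineage genes ranked above the cognate gene elsewhere: for CD4 and CD5 the best gene was Cd3g (0.468 and 0.520), while Cd4 stood at rank 24 (0.322) and Cd5 at rank 32 (0.317). For CD44 the best gene was Lgals1 (0.421), with Cd44 at 0.311. B220, an isoform-specific epitope of the Ptprc product, had the lowest rho, 0.038 with Ptprc, against 0.505 with Ebf1, a B-cell transcription factor. CD169, ERTR7 and Ter119 had no measured cognate gene.

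**Figure D2:**
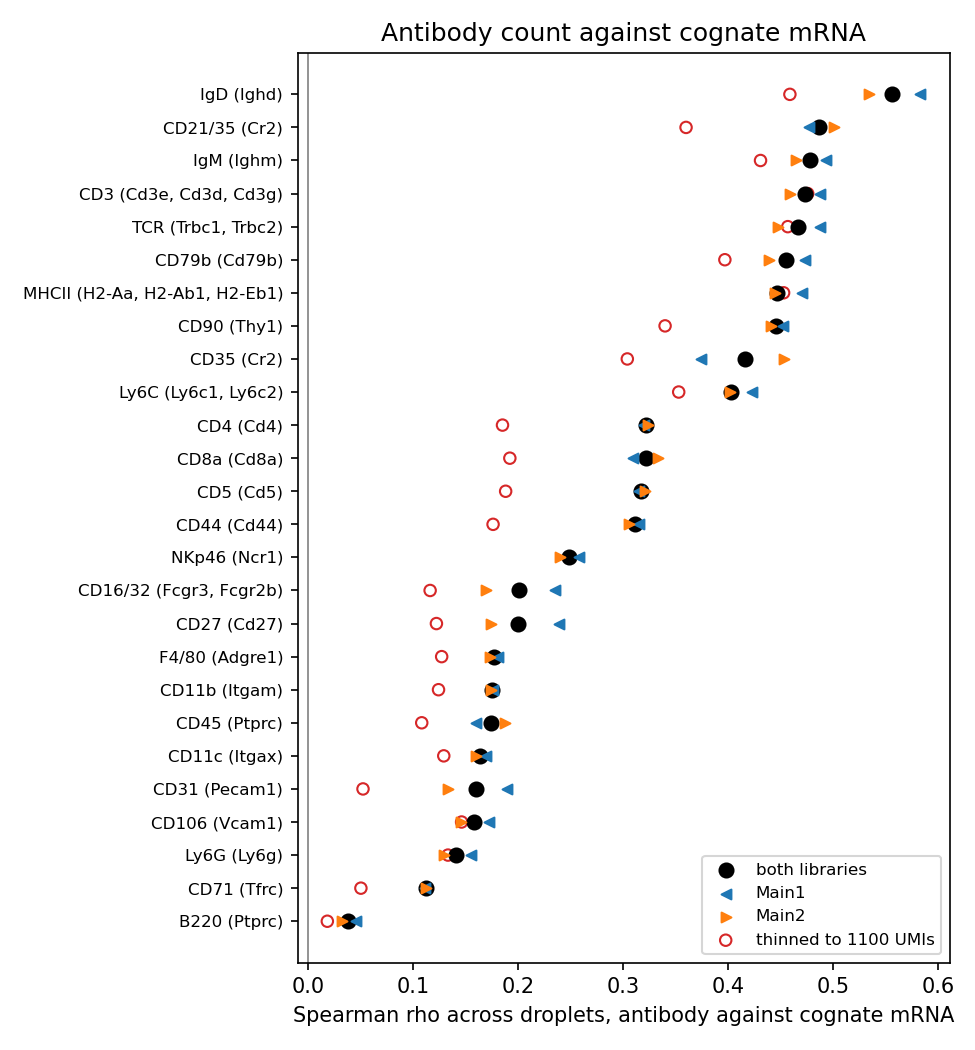
Spearman rho over droplets between each antibody and its cognate mRNA, for both libraries (black), Main1 and Main2 (triangles) and droplets thinned to 1100 UMIs (open circles). IgD with Ighd is highest at 0.556 and B220 with Ptprc lowest at 0.038, and thinning lowered most values.

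Detection of the cognate transcript in antibody-positive droplets differed widely between antigens. A UMI was found in 99.95% of droplets positive for MHC class II and 98.2% of those positive for IgM, but also in 90.2% and 86.2% of the negative ones. The shares in positive and negative droplets were 92.2% and 25.4% for CD79b, 81.4% and 8.72% for the T-cell receptor, 78.6% and 9.31% for CD3 and 75.2% and 12.9% for IgD. Others were found in few positive droplets. A Cd4 UMI was found in 28.7% of CD4-positive droplets (median depth 2693 UMIs) and in 0.50% of CD4-negative ones (1703 UMIs), and after thinning to 1100 UMIs in 10.4% and 0.284%. A Cd8a UMI was found in 45.5% of CD8a-positive droplets (median 3660 UMIs) and 0.714% of CD8a-negative ones (1719 UMIs). Adgre1, the gene of F4/80, had a UMI in 14.1% of F4/80-positive droplets and 0.405% of negative ones (medians 2977.5 and 1729 UMIs). The median rho was 0.309 in Main1 and 0.306 in Main2. It was 0.185 after thinning to 1100 UMIs, so its size depended on depth.

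For many antigens, but not for all, the transcripts with the highest ratios were those of the cells bearing it. In Ly6G-positive against Ly6G-negative droplets the neutrophil genes S100a8 and Ngp had log2 ratios of 7.34 and 7.33, and in CD11b-positive droplets S100a8 had 6.31 and Lyz2, the lysozyme gene of myeloid cells, 6.13. The haemoglobin gene Hba-a2 led for Ter119 (6.64) and CD71 (5.56). The complement gene C1qa led for CD106 (4.58) and F4/80 (4.06). Cd3g led for CD5 (5.14), the T-cell receptor (4.98) and CD27 (4.71), and Cd8b1 for CD8a (4.69). Hes1, a Notch target, had 1.64 for CD21/35. ERTR7 had a top ratio of 0.92, for Ighd. The top ratio for IgM was 2.32, for the acute-phase gene Saa3, but this was 0.005 in Main1 and 2.96 in Main2, so that it rested on 1 library. The ratios of NKp46 with Ighg1 (3.27 over both, 0.040 in Main1) were likewise those of Main2. CD45, whose gate was poor, had the erythroid genes Hba-a1 (2.64) and Rhd (2.54) among its named genes. Over all named pairs the median log2 ratio was 3.98.

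Droplets of the T gate numbered 575, 8.10% of all (7.48 to 8.76). Of these 283 were CD4-positive alone and 55 CD8a-positive alone. On a log-ratio within each droplet these gates were larger, with 954, 435 and 91 droplets. CD8 droplets were 5.16% of the T gate in Main1 (13 droplets, 2.78 to 8.66) and 13% in Main2 (42 droplets, 9.53 to 17.2). A further 211 were positive for both and were not used in the comparison of lineages. T-like droplets made up 96.5% of the CD4 gate and 89.1% of the CD8 gate.

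Genes of T-cell lineage and function separated the CD4 and CD8 gates. Cd8b1, the CD8 beta chain on chromosome 6 (71322788 to 71337494), had 17.4 CPM in the CD4 gate and 1335 CPM in the CD8 gate, and Cd8a had 3.17 and 371 CPM. Higher in the CD8 gate were Ccl5, a chemokine of cytotoxic and memory cells (log2 fold -3.55, SE 0.164, adjusted p 1.38e-90), and Nkg7, a cytotoxic granule gene (-2.68, SE 0.292, adjusted p 2.78e-17). Higher in the CD4 gate was Izumo1r, the folate receptor 4 of regulatory T cells (4.12, SE 0.604, adjusted p 1.89e-09). In the CD4 gate Cd4 had 152 CPM, the costimulatory receptor Tnfrsf4 (chromosome 4, 156013843 to 156016612) 181 CPM, the transcription factor Maf 99.8 CPM and the CD40 ligand gene Cd40lg 82.3 CPM, all with 0 UMIs in the CD8 gate. Against a floor of 3 UMIs these were at least 8.20-fold, 9.73-fold, 5.38-fold and 4.44-fold higher.

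In edgeR's test 55 of 2023 genes differed between the CD4 and CD8 gates, 30 higher and 25 lower in CD4. All 5 tested CD8 T genes were lower in the CD4 gate (5 when adjusted over the list alone), including Dapl1 at -1.15, with an adjusted camera p of 3.57e-17, and adjusted p = 0.614 with an estimated correlation. The gate itself sets Cd8a, and Cd8b1 encodes the partner chain of its product, so the count and the camera p are in part those of the gating, as they are for Cd4 in the CD4 T list. Of 5 CD4 T genes 4 were higher (5 adjusted over the list alone; camera adjusted p 3.75e-09), and of 3 regulatory T genes all 3, namely Ikzf2 (2.95), Tnfrsf4 and Tnfrsf18 (1.85), were higher (3 adjusted over the list alone; camera adjusted p 7.25e-06). The log2 ratio of Ikzf2 was 1.70 in Main1 and 3.56 in Main2. With an estimated correlation both lists had an adjusted p of 0.614. Of 10 naive T genes 1 was higher (Igfbp4, 1.42) and 1 lower (Dapl1), the same counts when adjusted over the list alone, with a camera adjusted p of 0.605. None of 10 T-cell genes passed, also when adjusted over the list alone, and Cd3e had a log2 fold of 0.08 (SE 0.236). Of their folds 9 were positive, with an adjusted camera p of 0.036, and adjusted p = 0.614 with an estimated correlation.

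Several named genes belonged to other cell types and sat in few droplets. Of the Hba-a2 UMIs in the CD4 gate 96.7% came from 1 droplet, as did 84.4% of the Igkc UMIs. In the CD8 gate 69.9% of the Lyz2 UMIs and 47.8% of the Irf8 UMIs came from 1 droplet. Fitted log2 folds were 4.01 for Hba-a2, 2.40 for Igkc, -3.59 for Lyz2 and -3.29 for Irf8. The remaining named genes higher in CD4 were Hba-a1 (2.98), Hbb-bs (2.58) and Ass1 (2.71). Those lower were Ppt1 (-2.38, with 45.9% of its CD8-gate UMIs in 1 droplet), Lgals3 (-2.03, with log2 ratios of -1.04 in Main1 and -2.10 in Main2), Cd7 (-1.70), H2-Ab1 (-1.03) and Cd74 (-0.93). As lists, erythroid (4 of 4) and plasma cell genes (3 of 3) were higher and 3 of 6 MHC class II genes lower, with 4, 3 and 4 when adjusted over the list alone. Their camera adjusted p values were 0.00145, 0.00537 and 0.00537, and with an estimated correlation each had an adjusted p of 0.614. In T-like droplets alone Hbb-bs was at 0.21, H2-Ab1 at -0.13 and Cd74 at -0.04, and neither these nor Igkc were called. The count of called genes was 74 on a log-ratio within each droplet (38 shared), 30 in T-like droplets alone (27 shared), 7 without the library block, 6 with DESeq2 and 4 in droplets under 4000 UMIs. In that order 41, 15, 2, 1 and 0 of these were higher in CD4 and 33, 15, 5, 5 and 4 lower.

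Marginal zone B cells lie at the border of the white pulp and follicular B cells within it. The antigen gates took 472 marginal zone droplets, 8.75% of the B gate (6.39% in Main1, 10.6% in Main2), and 1815 follicular droplets, 33.6% (36.5% and 31.4%). Genes of the marginal zone rose strongly: S1pr3, a sphingosine-phosphate receptor (chromosome 13, 51408639 to 51422797), had 66.0 against 4.08 CPM (log2 fold 4.09, SE 0.338, adjusted p 8.49e-09), Hes1 (chromosome 16, 30064384 to 30067796) 254 against 46.1 CPM (2.65, SE 0.167, adjusted p 9.98e-11), and Plac8 1660 against 332 CPM (2.47, SE 0.089, adjusted p 8.75e-15). The scavenger receptor gene Cd36 rose as well (3.28, SE 0.308). In follicular droplets Fcer2a, the gene of CD23, had 396 against 91.7 CPM (-1.94, SE 0.164, adjusted p 1.11e-08), the transcription factor Klf2 293 against 48.8 CPM (-2.30, SE 0.182, adjusted p 4.28e-09) and the proton channel gene Hvcn1 566 against 117 CPM (-2.15, SE 0.136). Of the gating antigens' own genes, Cr2 was higher in the marginal zone gate (1.74, SE 0.109) and Ighd lower (-1.44, SE 0.099), both as the gate sets them, which also counts towards the marginal zone and follicular lists.

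The edgeR test called 666 of 6506 genes, 375 higher and 291 lower in the marginal zone gate. All 9 tested marginal zone genes were higher (9 adjusted over the list alone), among them Cd9 (2.95), Dtx1 (2.00), Cd1d1 (1.90) and Mzb1. The camera adjusted p was 1.44e-56, and adjusted p = 0.419 with an estimated correlation. Of 8 follicular genes 7 were lower (7 adjusted over the list alone), including Ccr7 (-1.27) and Cxcr4 (-1.76), while Btg1 stood at 0.0074. That list had a camera adjusted p of 7.45e-16 and an adjusted p of 0.419 with an estimated correlation. Of 9 MHC class II genes 5 were slightly lower (7 adjusted over the list alone), such as Cd74 (-0.32) and H2-Ab1 (-0.28), with a camera adjusted p of 0.00156 and an adjusted p of 0.679 with an estimated correlation. Of 3 transitional B genes Vpreb3 (-1.50) and Ms4a4c (-1.31) were lower and Cd24a (0.48) higher, as also when adjusted over the list alone, with an adjusted camera p of 0.00197 and adjusted p = 0.555 with an estimated correlation. Of 8 immediate early or heat shock genes 4 were lower (4 adjusted over the list alone), with adjusted p values of 2.36e-04 and, with an estimated correlation, 0.555.

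The other named genes higher in the marginal zone gate were Serpine2 (4.90), I830077J02Rik (4.60), Nebl (4.19), Pclaf (3.84), Ptpn22 (2.77) and Dph5 (205 against 28.5 CPM). The 93 Pclaf UMIs in that gate came from 12 droplets, and its log2 ratio was 1.52 in Main1 against 2.91 in Main2. Lower were Cpne4 (-2.68), Trib2 (-2.12) and Lgals3 (-1.94). Haemoglobin genes were also lower, with Hba-a2 at -3.64, Hbb-bt at -3.35, Hba-a1 at -3.21 and Hbb-bs at -2.94, but 65.4% of the Hba-a2 UMIs in the follicular gate came from 1 droplet. In B-like droplets alone Hba-a2 stood at 0.60 and Hbb-bs at 0.24, neither of them called. As lists, 5 of 5 erythroid genes (5 adjusted over the list alone) and 5 of 6 neutrophil genes (5 adjusted over the list alone) were lower. Their camera adjusted p values were 5.26e-45 and 4.29e-04, and with an estimated correlation the adjusted p was 0.419 and 0.761. On a log-ratio within each droplet 953 genes were called (612 shared). DESeq2 called 203 genes, all 203 among the 666 and in the same direction, but it gave no adjusted p for 3027 of the 6506 genes.

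CD44, an adhesion receptor that marks antigen-experienced T cells, divided the CD4 gate into 94 high and 96 low droplets. The split was also one by droplet size: median UMIs were 2222 and 1761.5 and median antibody counts 3413 and 1746, and over all droplets CD44 had a rho of 0.605 with total UMIs. Genes of effector and memory cells were higher in CD44-high droplets. S100a6, a calcium-binding protein gene, had 711 against 17.0 CPM (log2 fold 5.23, SE 0.508, adjusted p 5.99e-22), Ccl5 1317 against 79.3 CPM (3.98, SE 0.302, adjusted p 5.79e-35) and the regulatory T-cell factor Ikzf2 555 against 45.3 CPM (3.58, SE 0.438, adjusted p 3.56e-14). The integrin gene Itgb1 (chromosome 8, 128685654 to 128733200) had 329 CPM against 0 UMIs, at least 19.4-fold higher, and Cd44 itself 85.1 CPM against 0 UMIs, at least 5.01-fold. Genes of naive T cells were lower: Igfbp4 (chromosome 11, 99041244 to 99054392) had 74.0 against 731 CPM (-3.29, SE 0.348, adjusted p 1.14e-18) and the transcription factor Lef1 178 against 873 CPM (-2.36, SE 0.271, adjusted p 5.94e-16).

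In edgeR's test 149 of 1110 genes differed by CD44 in the CD4 gate, 68 higher and 81 lower. That balance depended on the setting: 96 were higher and 47 lower with no UMI minimum, and 15 and 4 with DESeq2. It was 57 and 60 in T-like droplets alone and 102 and 109 on a log-ratio within each droplet. All 8 tested effector or memory genes were higher (8 adjusted over the list alone), with S100a4 at 5.35, Ahnak at 2.76, Nkg7 at 2.44 and Id2 at 1.82. The camera adjusted p was 2.88e-14, and adjusted p = 0.484 with an estimated correlation. Of 10 naive T genes 6 were lower, including Dapl1 (-3.05) and Ccr7 (-1.46), while adjusted over the list alone 7 were lower and 1 higher. That list had a camera adjusted p of 9.51e-07 and an adjusted p of 0.484 with an estimated correlation. Of 3 regulatory T genes Ikzf2 and Tnfrsf4 (3.45) were higher and Tnfrsf18 (0.27) was not called. Both counts were the same when adjusted over the list alone, with an adjusted camera p of 0.00126 and adjusted p = 0.484 with an estimated correlation. Of 4 MHC class II genes 3 were lower (4 adjusted over the list alone), with an adjusted camera p of 0.00610, and adjusted p = 0.484 with an estimated correlation. In the CD44-low set 45.5% of the H2-Ab1, 51.1% of the H2-Eb1 and 50% of the Cd74 UMIs lay in 1 droplet.

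Of the other named genes, the plasma cell genes Iglc1 (5.54), Jchain (3.12), Ighm (3.01) and Igkc (2.52) were higher and the haemoglobin genes Hba-a2 (-7.07), Hba-a1 (-6.77), Hbb-bt (-5.52) and Hbb-bs (-5.17) lower in CD44-high droplets. Single droplets carried most of these UMIs: 98.6% of the Iglc1 UMIs and 90.6% of the Igkc UMIs in the CD44-high set, and 98.9% of the Hba-a2 UMIs in the CD44-low set, came from 1 droplet each. Within T-like droplets Igkc stood at -0.12. Ly6c2 (4.41) had 69.0% of its UMIs in 1 droplet, and Cytip (-1.55) and Rbm38 (-1.51) were lower. The count of called genes was 211 on a log-ratio within each droplet (131 shared), 117 in T-like droplets alone (108 shared), 81 with CD44 quartiles, 61 without the library block, 19 with DESeq2 (no adjusted p for 87 genes) and 13 in droplets under 4000 UMIs. Under that limit the fitted folds of S100a6 (5.13), Ccl5 (4.39), Igfbp4 (-3.25) and Lef1 (-2.42) kept direction and similar size. Their edgeR adjusted p values were 0.036, 0.041, 0.041 and 0.052. Median UMIs of the 2 sets still differed there (1983 and 1761.5).

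**Figure D3:**
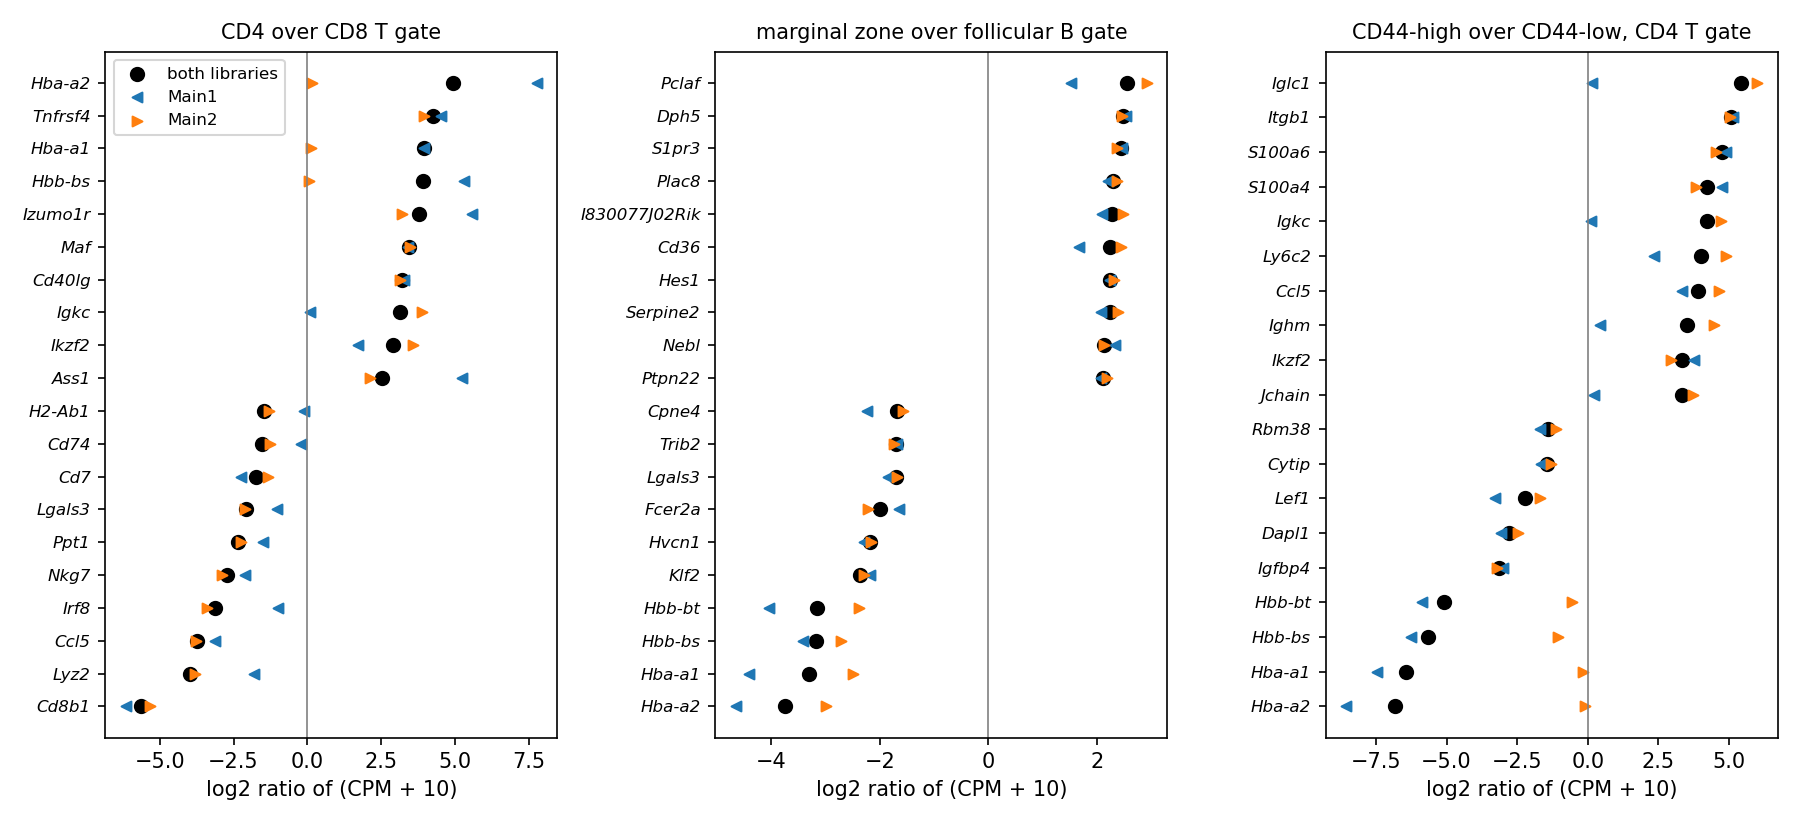
Log2 ratio of (CPM + 10) of named genes in 3 gated comparisons, for both libraries (circles), Main1 (left triangles) and Main2 (right triangles). S1pr3 and Hes1 lie close together in both libraries, whereas Hba-a2 in the T gates lies far from 0 in Main1 alone.

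In the CD8 gate the CD44-high set had 18 droplets, 2 of them from Main1, and the CD44-low set 19, 4 of them from Main1. Median UMIs were 4107 and 2089 and median antibody counts 4201.5 and 2213. Gzma, a granzyme gene (chromosome 13, 113093825 to 113100981), had 2399 CPM in the high set and 0 UMIs in the low set, at least 32.7-fold higher, with 192 of its 193 UMIs from Main2. Lgals1, the gene of galectin-1, had 1703 against 196 CPM (log2 fold 3.18, SE 0.616, adjusted p 1.95e-05), Hmgb2 1081 against 171 CPM (2.67, SE 0.634, adjusted p 0.00101) and AW112010 2287 against 808 CPM (1.43, SE 0.428, adjusted p 0.022). The MHC class II genes H2-Aa (2.80), H2-Ab1 (3.16), H2-Eb1 (3.51) and Cd74 (2.97) were all higher, 4 of 4 also when adjusted over the list alone. Of 5 effector or memory genes Ccl5 (2.63) and S100a6 (4.59) were higher, also when adjusted over the list alone, but in Main1 Ccl5 had 1209 against 1233 CPM and S100a6 0 UMIs on either side, so both rested on Main2. The camera adjusted p was 1.63e-06 for class II and 0.00366 for effector or memory genes, and with an estimated correlation both had an adjusted p of 0.513.

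In the CD8 gate edgeR called 14 of 298 genes, all higher in CD44-high droplets. Myeloid genes were 4 of them: Cst3 (4.10, adjusted p 4.44e-10), Lyz2 (3.75, with 93.8% of its CD44-high UMIs in 1 droplet), Apoe (3.31) and Psap (1.99), singled out after their values were seen. In Main1 Cst3 had 110 against 247 CPM, Psap 220 against 370 and Lyz2 0 against 493, with Apoe at 0 on either side. All 4 therefore rested on Main2. Of the 18 CD44-high droplets 14 were T-like, against all 19 CD44-low ones. The 10 named genes with the lowest ratios, such as Limd2 (-1.34, adjusted p 0.073), Ltb (-0.82, adjusted p 0.550) and Btg1 (-0.75, adjusted p 0.562), did not pass. Of the named genes with the highest ratios Hmgn2 (2.07), Sh3bgrl3 (1.56), Gdi2 (1.55), Clic1 (1.55), Atox1 (1.54) and Arpc2 (1.42) did not pass either. The count was 13 with a minimum of 10 UMIs and 11 with none. It was 0 in T-like droplets alone, with DESeq2, without the library block, with CD44 quartiles, in droplets under 4000 UMIs and on a log-ratio within each droplet. Unadjusted p under 0.05 was met there by 44, 2, 14, 26, 17 and 50 genes. The called genes did not all lose their folds in T-like droplets alone. Gzma (8.83) and Lgals1 (3.635) had an edgeR adjusted p of 0.055 there, Hmgb2 (2.72) and AW112010 (2.04) of 0.069. The median log2 ratio of the 4 class II genes was -0.61 in T-like droplets. In Main1 alone the log2 ratio was -5.25 for H2-Ab1 and -0.57 for Cd74, so the class II difference came from Main2. For H2-Ab1 that was 0 UMIs in 2 CD44-high droplets against 370 CPM in 4 CD44-low droplets with 8110 UMIs in total. So few UMIs lay behind it that the pseudocount set its size.

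Main1 and Main2 were close within classes, with a Pearson r over log2 CPM of 0.992 across 8483 genes in B-like droplets and 0.984 across 6343 genes in T-like droplets. These are correlations across genes, which are not independent replicates. In B-like droplets Main1 had the higher level of the heat shock genes Hspa8 (1442 against 706 CPM, count ratio 1.97 to 2.12), Hsph1 (40.1 against 12.7 CPM, 2.40 to 4.18) and Hspa1a (66 UMIs against 2, 10.9 to 345), and of Gm26825 (139 against 50.3 CPM) and AY036118 (75.6 against 28.8 CPM). Main2 had more of the cold-inducible RNA-binding genes Cirbp (345 against 175 CPM) and Rbm3 (658 against 388 CPM), of the immediate early gene Fos (108 against 49.1 CPM), and of Cpt1a (20.0 against 6.51 CPM) and Lst1 (158 UMIs against 62). With 1 library a side these differences have no replicate check.

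In T-like droplets Gm26825, Hsph1 and AY036118 were again higher in Main1 (log2 ratios 1.22, 0.94 and 0.93), with Penk (1.33), the enkephalin precursor gene, and Ly6a (0.94). Cirbp (-1.16) and Fos (-0.98) were again higher in Main2. Gzma (196 against 30.6 CPM, -2.34) and the NK receptor gene Ncr1 (-1.11) were higher in Main2, as was Jchain (-1.01), 36.7% of whose Main2 UMIs came from 1 droplet. Thinned to 1100 UMIs, Jchain stood at -0.50, Ly6a at 1.71, Ncr1 at -2.02 and Fos at -1.65. Among antibodies on B-like droplets the mean count of Ly6C was 3.36 times higher in Main1, although its median was 13 against 10. MHC class II had medians of 1081.5 and 814, and CD21/35 of 95 and 108.

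**Figure D4:**
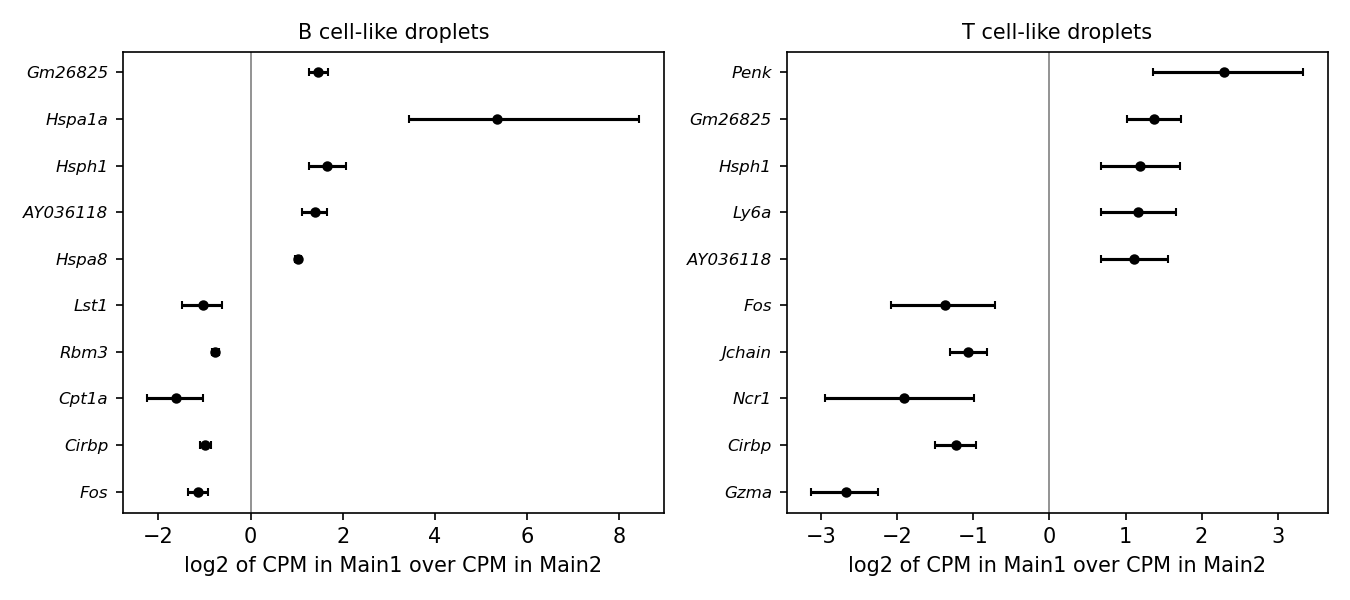
Log2 of CPM in Main1 over CPM in Main2 for the 10 named genes of B cell-like (left) and T cell-like droplets (right), with 95% counting intervals as bars. Heat shock genes such as Hspa8 lie above 0 and Cirbp and Fos below 0.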

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

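Of the explanations weighed here, the tests of Trbc1 with Trbc2, of random loading, of a mix of CD4 and CD8 cells, of age-associated genes and of B220 were chosen only after the results were seen.

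Of the 575 T-gate droplets 211 carried both CD4 and CD8a, 36.7% (32.8 to 40.8), with 94 in Main1 and 117 in Main2. Mature T cells keep 1 of these coreceptors, so both on 1 droplet was unforeseen. These droplets had a median of 3558 UMIs, against 1897 in the CD4 gate and 2327 in the CD8 gate. Their median antibody count was 6311, against 2379 and 2742. Their Cd4 level was 85.6 CPM, against 152 CPM in the CD4 gate and 0 UMIs in the CD8 gate. Their Cd8a plus Cd8b1 level was 791.6 CPM, against 20.6 CPM in the CD4 gate and 1706.1 CPM in the CD8 gate. Of the 211, 33 held UMIs of both Cd4 and Cd8a or Cd8b1.

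Just 1 of the antibodies bound without its transcript in all these droplets was unlikely as the source, since the lower counting limits were 3.66 for Cd4 over the CD8 gate, which had 0 UMIs, and 22.3 for Cd8a with Cd8b1 over the CD4 gate. These are sums over droplets, which a mix of CD4 cells and CD8 cells that each bound the other antibody would also meet. Such a mix was unlikely as the whole source: at 1100 UMIs 7 of 22 droplets with a Cd4 UMI, 31.82% (13.9 to 54.9), also held Cd8a or Cd8b1, against 2.47% (upper limit 5.03) in the CD4 gate. With so few droplets, a mix in part of them stays open. By Trbc1 and Trbc2, more than 1 T cell in a droplet could not be told from a single cell. At 1100 UMIs 37.31% (30.6 to 44.4) held both, against 33.0% in the CD4 gate and 41.25% in simulated sums. These 2 references lay too close together for the test to decide. Antibody counts above those of either gate, and Cd4 and Cd8 levels between the gates, go with more than 1 T cell. No test was set on those values. Without thinning the share was 75.6%, against 47.6% in the CD4 gate, 57.1% in the CD8 gate and 81.3% in simulated sums, but there depth differed as well. Droplets loaded at random with 2 cells would have given many more T-cell and B-cell pairs than were seen. Droplets positive for CD3, a B-lineage antigen and CD4 or CD8a numbered 346, against 211 with CD4 and CD8a. That was a ratio of 1.64 (1.38 to 1.96) where at least 3 was required. That test would be weakened if droplets pairing T and B cells had been removed in part before deposit. T cells that stuck together before loading were not tested.

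The CD44 difference was not the same in the CD8 and the CD4 gate for 5 of 1432 genes in edgeR's interaction test (75 at unadjusted p under 0.05). H2-Eb1 (4.51, adjusted p 0.00264), Cd74 (3.43, adjusted p 0.00264) and H2-Ab1 (4.19, adjusted p 0.00308) had larger log2 differences in the CD8 gate, in part since they were lower with CD44 in the CD4 gate (-1.24, -1.02 and -1.11), where 51.1%, 50% and 45.5% of their CD44-low UMIs lay in 1 droplet. Ly6c2 (-4.14, adjusted p 0.020) and Igkc (-3.76, adjusted p 0.049) had larger ones in the CD4 gate, but 69.0% of the Ly6c2 and 90.6% of the Igkc UMIs of its CD44-high set lay in 1 droplet, and Igkc stood at -0.12 in T-like droplets alone. Class II genes belong to antigen-presenting cells, and their rise in a T-cell gate was unforeseen.

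Droplets of another class in the CD8 gate are a likely source of the class II genes. With T-like droplets alone the median log2 ratio of H2-Aa, H2-Ab1, H2-Eb1 and Cd74 was -0.61, against 3.38 in the whole gate. For that value the CD44 tertiles were cut anew among T-like droplets, giving 17 high and 17 low ones. Of the 1208 UMIs of these genes in the original CD44-high set, 95.8% lay in 4 droplets outside the T-like class. A single droplet is an unlikely source, since without the conventional DC1-like droplet that held 48.2% of these UMIs the median was still 2.62.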

How the results depend on the processing

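The median antigen to mRNA rho of 0.311 was 0.299 on a log-ratio within each droplet, 0.185 after thinning, 0.230 in droplets under 4000 UMIs, and 0.306 to 0.309 in single libraries. For B220 with Ptprc it turned to -3.86e-03 within droplets. The B-like share was 73.6 to 75.8% in single libraries. B220-positive B-like droplets were 92.8% with k-means gates and 96.6% within droplets, against 99.0%. Among antibody-positive genes the median log2 ratio was 3.37 with k-means gates and 3.92 to 3.97 in single libraries. With k-means gates for CD45, Hba-a1 (-6.15) and Rhd (-1.73) turned negative. Gm26825 in B-like droplets stood at 0.915 with a pseudocount of 50.

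The T gate of 575 droplets, 283 CD4 and 55 CD8, became 954, 435 and 91 within droplets. For CD4 against CD8 T cells 55 genes became 74 within droplets (38 shared), 35 with a minimum of 10 UMIs, 32 with none, 32 with k-means gates, 30 in T-like droplets alone, 7 with no replicate block, 6 with DESeq2 and 4 in droplets under 4000 UMIs. Both populations come from the same libraries, so the block was kept. Igkc was at -7.94e-04 in T-like droplets alone, and H2-Ab1 (1.08) and Cd74 (1.37) turned positive under 4000 UMIs.

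For marginal zone against follicular B cells 666 genes became 953 within droplets, 874 with a minimum of 10 UMIs, 837 with none, 784 in B-like droplets alone, 697 under 4000 UMIs, 579 with the narrower gate, 509 with no replicate block and 203 with DESeq2, which gave 3027 genes no adjusted p. Haemoglobin genes turned positive in B-like droplets alone and in droplets under 4000 UMIs: Hbb-bt 0.11 and 0.29, Hbb-bs 0.24 and 0.27, Hba-a1 0.58 and 0.62, Hba-a2 0.60 and 0.88. The last was called in that direction (edgeR adjusted p 0.00852).

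For CD44 in the CD4 gate 149 genes became 211 within droplets, 177 with a minimum of 10 UMIs, 143 with none, 117 in T-like droplets alone, 81 with quartiles, 61 with no replicate block, 19 with DESeq2 and 13 under 4000 UMIs, and Igkc turned to -0.12 in T-like droplets alone. In the CD8 gate 14 genes became 13 with a minimum of 10 UMIs, 11 with none, 0 with no replicate block, 0 with DESeq2, 0 within droplets, 0 with quartiles, 0 in T-like droplets alone and 0 under 4000 UMIs. Cd74 turned to -0.50 in T-like droplets alone. Between single libraries Ccl5 ran from -0.028 to 3.11, H2-Ab1 from -5.25 to 4.07, H2-Aa from -4.68 to 2.99 and Cd74 from -0.57 to 3.55. The low ends of H2-Ab1 and H2-Aa were 0 UMIs against 370 and 247 CPM in Main1. They rested on very few UMIs and are not measured reversals.

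Of 1975 single values compared, 1461 were kept, 327 moved, 167 were weaker, 0 stronger and 20 reversed. A fitted fold counted as kept on its direction and call, whatever its size, and a ratio, share or rho on its size alone. Of the kept values 143 came from leaving out the Scrublet calls, which left the gated populations unchanged. The cause of the changes was not tested. The B-like share, the B220-positive share and Gm26825 were picked for this section after the data were seen.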

Other observations

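A B-like cluster of 291 droplets had no name from the fixed markers and stood apart in both layers. S100a6 had 443 CPM there, 20.2 times (17.0 to 24.0) its level in other B-like droplets, and Spn, the gene of CD43, 31.9 against 5.57 CPM. The transcription factor genes Bhlhe41 (267 against 7.79 CPM) and Zbtb32 (111 against 2.13 CPM) and the interleukin-5 receptor gene Il5ra (62.6 against 6.28 CPM) were higher, while Fcer2a (71.5 against 343 CPM) and Cr2 (115 against 384 CPM) were lower. The CD5 antibody had a median of 12 counts against 4 and CD44 105 against 36. IgD had 119 against 546, and IgM was equal at 32. By the CD5 gate 23.4% (18.6 to 28.7) of the cluster was positive, against 2.69% of other B-like droplets. Most of its droplets were therefore CD5-negative.

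B-1 B cells are a likely identity: 7 of 8 listed genes reached at least 2 times the level of other B-like droplets, though Cd5 and Itgam did so on 4 and 3 UMIs and Ctla4 had 0 UMIs. The CD5 antibody counts and leading genes of this cluster had been seen when that list was set, but not its gene ratios. Age-associated B cells could not be told apart on their list, of which 3 of 6 genes (Zbtb32, Fcrl5 and Itgam) reached that level. Droplets holding 2 B cells of the usual B220 level are unlikely, since the ratio of median B220 counts was 0.38. That ratio cannot decide on cells low in B220 that share a droplet, so more than 1 cell in a droplet stays open. The ratio of median UMIs, 1.51, met the criterion first set for it. Memory B cells were not tested.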
